A study of Mus musculus with 24 samples.

How the data were processed

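Total and metabolically labelled RNA were sequenced, and total RNA was analysed here, in bone marrow-derived basophils from wild-type (WT) mice and from mice lacking tristetraprolin (TTP-KO), the RNA-binding protein encoded by Zfp36. Per the labels' protocols, marrow was cultured for 7 days in 0.3 ng/mL IL-3, and TNP-specific IgE at 1 µg/mL and 4-thiouridine (s4U, a uridine analogue that marks new RNA) at 150 µM were added on day 6. Cells carrying CD49b were then enriched with magnetic beads, given TNP-coupled ovalbumin at 10 ng/mL for 1.5 h with s4U, washed, and kept for 0, 1, 2 or 4 h without antigen or s4U. RNA was alkylated with 10 mM iodoacetamide for 15 min at 50 °C, and 65 ng went into QuantSeq 3' mRNA V2 libraries with unique dual indices, read on a NovaSeq sequencer. The labels give 8 groups of 3 libraries, 24 in all. They do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

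The submitters' processing notes name cutadapt 3.5, STAR 2.7.10a, SAMtools and the build GRCm39, with no role or order. The series' design text names GRAND-SLAM and grandR for the half-lives. The gene annotation and any filter before deposit are not given in the sources used here. The deposited table holds 15737 genes, with expected counts of reads per gene and library that were not normalized, of which 12.8% were not whole. The table names its columns by genotype, time and a letter A, B or C, and the labels number the replicates 1 to 3. Nothing ties letters to numbers, so each column of reads was taken as a library of its group and is named in the text by its letter. For columns tied to a group and not to a sample, 1 measure was kept, the reads. The other 144 columns of per-sample values, which per the file headers hold GRAND-SLAM's new-to-total ratio (the share of a gene's RNA estimated to carry s4U) with its interval and shape parameters, were not used here. The decay slopes, half-lives and labelled fractions planned from them are therefore not reported. They were left out because of the mapping, after their values had been seen.

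Libraries held 8839260 to 25372890 reads. The 3' tags carry no molecular identifiers in this table, so floors cover counting error only. Over the 24 pairs of libraries of 1 group, chi-square per degree of freedom lay between 30.2 and 78.7, so no library repeated another. The table listed 0 mitochondrial genes. Symbols were taken from the table, where 19 genes had none and 27 had a repeated symbol.

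Total RNA was tested in R 4.3.3 with edgeR 4.0.16. Reads were rounded, scaled with TMM factors and filtered with filterByExpr, which left 12936 genes, and 1 quasi-likelihood fit held a mean for each of the 8 groups over all 24 libraries. Contrasts gave KO against WT at each time, 1, 2 and 4 h against 0 h in each genotype, and the difference between the genotypes' changes from 0 to 4 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are given with standard errors, and levels as TMM-scaled CPM (read counts scaled to a common library total), as mean ± SD of 3 libraries. Where all libraries of a group held 0 reads of a gene, the fold is given as a lower bound against 3 counts over the group, which corresponds to 0.0451 to 0.0726 CPM.

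The 24 gene lists were basophil cytokines and chemokines, TTP targets from earlier work, immediate early genes, NF-kB targets and feedback, calcineurin NFAT response, RNA decay regulators, basophil identity and granule, lipid mediator synthesis, survival and apoptosis, p53 response, unfolded protein and integrated stress response, interferon response, ribosomal proteins, oxidative phosphorylation, glycolysis, mitochondrial transcripts, cell cycle, and markers of mast cells, NK and T cells, monocytes and macrophages, neutrophils, eosinophils, dendritic and B cells, and erythroid and progenitor cells. Lists share members: Il4, for example, is in the cytokine, TTP target and NFAT lists. Each list with at least 5 tested members was tested for KO against WT at the 4 times with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over 92 pairs of list and time, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. Genes with the TTP motifs TATTTAT or TTATTTATT in annotated 3' UTRs were compared with other genes by camera (8 tests) and by 10000 permutations of motif membership within 20 bins of 3' UTR length. The annotation used for this was GENCODE M21 (GRCm38), matched by gene ID for 15680 of the 15737 genes. As that is not the build the submitters name, no coordinates are given, and motif positions were not compared with theirs.

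Genes to be named were set by rule. The 14 genes Zfp36, Il4, Il13, Il6, Tnf, Ccl3, Ccl4, Csf1, Areg, Ptgs2, Plaur, Cxcl2, Zfp36l1 and Zfp36l2 were named whether or not they passed. At 0 h and 4 h, the 8 called genes with the largest change each way were added, and 4 each way in other comparisons. These needed a mean of at least 5 CPM and, outside the interaction, all libraries of 1 group beyond all of the other. From each list came up to 3 called members with the smallest adjusted p, or otherwise 2 with the highest level. The 532 genes with only a predicted or clone symbol were counted but not named. Further called members of a list, and the genes higher in KO at every time, were named as examples after their values were seen. Of the genes this rule names, 1 is not reported here. The grouping, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

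The procedures were tested on simulated data built from the real libraries. For KO against WT at 4 h, with 12564 genes, 31% of 100 genes changed by a log2 of 1 and 71% of 100 changed by a log2 of 2 were recovered, with 1 false call. A list of genes shifted by a log2 of 1 was called among 20 lists without a shift, of which 0 were called. Genes were simulated independently, so this does not test list calls where the members vary together.

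Alternatives tried were DESeq2 1.42.0, other size factors, library size only, other count filters, fits of only the groups compared, and leaving out each library. Added after the data were seen were fits without the 2 smallest libraries. Python 3.11.15 with pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the figures.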

Results

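Basophils from WT and TTP-KO mice, loaded with IgE, were exposed to antigen and s4U for 1.5 h and then followed for 0, 1, 2 and 4 h after both were washed away. Each of the 8 groups of genotype and time held 3 libraries. Reads per library ranged from 8839260 to 25372890, and the smallest libraries were KO 4 h B (8839260) and KO 4 h C (10878380). The 15 most abundant genes took 17.4% to 22.5% of the reads, with Actb, the cytoskeletal actin gene, at 4.10% to 6.86%. Values below are TMM-scaled CPM as mean ± SD of 3 libraries, log2 changes ± SE, and adjusted p from edgeR, unless said otherwise. They describe total RNA: the labelled share of each gene's RNA was not used here, so no half-lives are given.

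Zfp36 (ENSMUSG00000044786), the gene that encodes TTP, still gave reads in every KO library. At 0 h it stood at 237 ± 28 CPM in WT, with libraries from 219 to 269, and at 185 ± 26 in KO, with libraries from 158 to 210 (log2 change -0.36 ± 0.24, adjusted p = 0.796). It was lower in KO at 1 h, by -1.45 ± 0.24 (edgeR adjusted p = 0.000116), where KO libraries lay between 36.0 and 58.5 CPM and WT libraries between 104 and 147. At 2 h the change was -0.92 (adjusted p = 0.0652), and at 4 h -0.87 (edgeR adjusted p = 0.0422), where KO libraries A and C were at 22.4 and 28.1 CPM, library B at 62.1, and WT libraries at 58.4 to 78.2. The 3' tags may lie outside the disrupted part of the gene, so these reads do not check the genotype.

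The first comparison asks how RNA levels differed between the genotypes at the end of the antigen pulse. At 0 h, RNAs for inflammatory mediators and for macrophage-type proteins were higher in KO. Ptgs2, which encodes the inducible cyclooxygenase, stood at 4515 ± 135 CPM in KO against 1920 ± 177 in WT. Tnf stood at 820 ± 74 against 360 ± 41, Il6 at 5853 ± 198 against 3703 ± 164, and the chemokine gene Ccl3 at 38379 ± 1321 against 19923 ± 1432. Il4 (ENSMUSG00000000869), the type 2 cytokine for which basophils are best known, was alike in both, at 3246 ± 512 CPM in KO and 3181 ± 181 in WT (log2 change 0.03 ± 0.11, adjusted p = 1). Apoe, a lipid carrier made by macrophages, was higher in KO by 2.78 ± 0.18 (edgeR adjusted p = 4.55e-16), at 366 ± 32 CPM against 53.5 ± 4.0.

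In this comparison 68 of 12936 genes passed the edgeR threshold, 58 higher and 10 lower in KO. DESeq2 called 133 higher and 94 lower, and a fit of only the groups compared 91 higher and 25 lower. Of the 36 basophil cytokine and chemokine genes, 10 were higher and 0 lower (14 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.02e-15). Beyond Il6, Tnf and Ccl3 these included the neutrophil attractant Cxcl2 (0.95), the growth factor Areg (0.45) and the monocyte attractant Ccl2 (2.10), while Il13 (0.46, adjusted p = 0.59), Ccl4 (0.28, adjusted p = 0.4) and Csf1 (0.29) did not pass. Of the 49 TTP targets from earlier work, a list that shares most of its called members with the cytokines, 12 were higher and 0 lower (16 higher adjusted over the list alone; adjusted p = 4.24e-20). They included the kinase genes Pim1 (0.51) and Plk3 (0.80) and the cytokine genes Lif (1.03) and Osm (1.02). Plaur (0.13, adjusted p = 1) and the TTP relatives Zfp36l1 (0.33) and Zfp36l2 (0.19) did not pass.

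Of the 20 monocyte and macrophage markers, 9 were higher in KO at 0 h (13 adjusted over the list alone; median log2 2.13, camera adjusted p = 8.84e-42). Among them were the mannose receptor gene Mrc1 (4.67 ± 1.06), Ms4a7 (3.78 ± 0.93), the complement genes C1qb (2.78) and C1qc (2.28), the lysosomal protease gene Ctss (2.61 ± 0.19), the lysozyme gene Lyz2 (1.02 ± 0.12) and Csf1r (1.67), the receptor of macrophage colony-stimulating factor. The summed level of these 20 markers was 2503 ± 41 CPM in KO and 1168 ± 21 in WT. It was higher in the same libraries as the cytokine and TTP target genes above, several of which macrophages also make. Other large increases were in Fabp4, a fatty acid carrier of macrophages and fat cells (5.30 ± 1.15), Plekhg2 (5.58 ± 1.00), Rpap1 (4.60 ± 1.07), Pdpn (3.19 ± 0.66) and the membrane metalloproteinase gene Mmp14 (3.14 ± 0.54). Edn1, which encodes endothelin, had 0 reads in WT at 0 h and was at least 91.0-fold higher in KO. Rpap1 and Edn1, with low means of 7.59 and 10.3 CPM, did not pass at 1, 2 or 4 h. The largest decreases were in the chemokine receptor gene Cxcr2 (-1.10 ± 0.21), the mast cell tryptase gene Tpsb2 (-0.98 ± 0.17), Arap1 (-0.98 ± 0.23), Lfng (-0.84 ± 0.21), the myeloid transcription factor gene Cebpa (-0.73 ± 0.14), Parvb (-0.71 ± 0.15), the cyclin gene Ccnd3 (-0.58 ± 0.12) and Mxd1 (-0.46 ± 0.11). The naming rule required that in each of these the 3 KO libraries lie beyond the 3 WT libraries.

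Among other lists at 0 h, immediate early genes (44) tested higher in KO with 0 members past the edgeR threshold (1 adjusted over the list alone; camera adjusted p = 0.00253, adjusted p = 0.0556 with an estimated correlation). The calcineurin NFAT response (24 genes) tested higher with Ptgs2 alone past the threshold (adjusted p = 0.0162, adjusted p = 0.0843 with an estimated correlation), but its mean was -0.17 and its median 0.21. Ribosomal proteins (62) tested lower with 0 members past the threshold (median -0.12, adjusted p = 0.000174, adjusted p = 0.499 with an estimated correlation). The antigen-presentation genes Cd74 (0.83 ± 0.18) and H2-Aa (0.91 ± 0.19), were higher, and the dendritic and B cell list that holds them tested higher (adjusted p = 0.044, adjusted p = 0.069 with an estimated correlation).

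At 1 and 2 h after the wash, the comparison asks whether the difference persisted without antigen. At 1 h cytokine RNA differed as follows. Il4 stood at 6210 ± 464 CPM in KO against 3192 ± 635 in WT (0.96, edgeR adjusted p = 6.56e-08), and Il13 at 772 ± 150 against 307 ± 15 (1.33, edgeR adjusted p = 1.25e-05). Areg was at 1898 ± 95 against 701 ± 82, Cxcl2 at 4857 ± 189 against 1612 ± 262 and Ccl3 at 40188 ± 3610 against 12976 ± 827. The difference of the changes from 0 to 1 h was also tested with edgeR, a test chosen only after the result was seen. By it the gap widened for Il4 (adjusted p = 0.00235), Areg (adjusted p = 0.000726) and Ccl3 (adjusted p = 0.00378). It did not pass for Il13 (adjusted p = 0.97) or Cxcl2 (adjusted p = 0.0609). At 2 h Il4 still stood at 5320 ± 402 CPM in KO and 1668 ± 226 in WT (1.67, edgeR adjusted p = 1.81e-15), and Il13 differed by 2.01 (adjusted p = 5.55e-10).

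At 1 h 65 genes passed, 52 higher and 13 lower, and at 2 h 67 passed, 53 higher and 14 lower. With library size only in place of TMM, 48 were higher and 23 lower at 1 h, and 48 higher and 31 lower at 2 h. DESeq2 called 107 higher and 95 lower at 1 h, and 133 higher and 95 lower at 2 h. A fit of only the groups compared called 59 higher and 7 lower at 1 h, and 37 higher and 4 lower at 2 h. Of the TTP targets, 16 were higher and 1, Zfp36 itself, lower at 1 h (24 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.93e-42), and 12 were higher and 0 lower at 2 h (19 and 2 adjusted over the list alone; adjusted p = 1.94e-28). Plaur, the urokinase receptor gene, was among them at 1 h (1.22) and 2 h (0.73), and the chemokine gene Ccl4 passed at 1 h (0.51, adjusted p = 0.00142) and 2 h (0.44, adjusted p = 0.0123). Of the cytokine list, 12 were higher at 1 h and 11 at 2 h, with 0 lower at both times (15 higher and 2 lower, then 11 and 1, adjusted over the list alone; camera adjusted p = 7.24e-32 and 1.81e-23). The NFAT list tested higher at both times, with Ptgs2 and Il4 past the threshold (adjusted p = 0.00248 at 1 h and 7.03e-06 at 2 h). At 1 h its mean was -0.04 and its median 0.18. Immediate early genes also tested higher, with 0 members called (adjusted p = 0.00248 at 1 h, adjusted p = 0.0556 with an estimated correlation, and 0.000544 at 2 h; 4 members higher at 1 h, and 6 higher and 1 lower at 2 h, adjusted over the list alone).

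The macrophage markers remained apart, with 7 of 20 higher at 1 h and 8 at 2 h (12 at 1 h, and 14 with 1 lower at 2 h, adjusted over the list alone; median log2 1.56 and 1.81, camera adjusted p = 2.46e-42 and 1.08e-35). Their sum was 2372 ± 129 CPM in KO against 1003 ± 75 in WT at 1 h, and 1999 ± 196 against 860 ± 14 at 2 h. At 1 h Atp6v0d2 (3.54 ± 0.87) and Ms4a6d (3.29 ± 0.52) gave large increases, with Pus7 at least 47.6-fold higher. Pus7, with a low mean of 6.36 CPM, did not pass at 0, 2 or 4 h. The glycine transporter gene Slc6a9 (-0.91 ± 0.21), Glipr2 (-0.88 ± 0.18) and Rnf128 (-0.84 ± 0.19) gave large decreases after Zfp36. At 2 h large increases were in Sdc1 (5.49 ± 1.36), Mrc1 (4.38 ± 1.02) and Plekhg2 (3.85 ± 0.93), with Ly6i at least 248-fold higher. Large decreases at 2 h were in Tep1 (-5.77 ± 1.18), the UDP-sugar receptor gene P2ry14 (-1.20 ± 0.20), Igkc (-1.10 ± 0.25) and Cxcr2 (-0.93 ± 0.21). Ly6i, Tep1 and Sdc1, with low means of 5.29, 6.79 and 7.62 CPM, did not pass at 0, 1 or 4 h, and neither did P2ry14 and Igkc. Atp6v0d2, with a mean of 10.5 CPM, and Slc6a9 did not pass at 0, 2 or 4 h. Of the 36 basophil identity and granule genes, 1 was lower at 2 h: Ms4a2, which encodes the beta chain of the IgE receptor (-0.64; list adjusted p = 0.0239, adjusted p = 0.0657 with an estimated correlation). At 2 h the cell cycle list tested lower with 0 of 34 members called (adjusted p = 0.0058, adjusted p = 0.0503 with an estimated correlation) and the mast cell list lower (adjusted p = 0.033, adjusted p = 0.0657 with an estimated correlation). Oxidative phosphorylation tested higher at 1 h (adjusted p = 7.3e-05) and at 2 h (adjusted p = 0.00117, adjusted p = 0.0817 with an estimated correlation), and ribosomal proteins higher at 2 h (median 0.13, adjusted p = 2.01e-05, adjusted p = 0.465 with an estimated correlation).

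**Figure D1:**
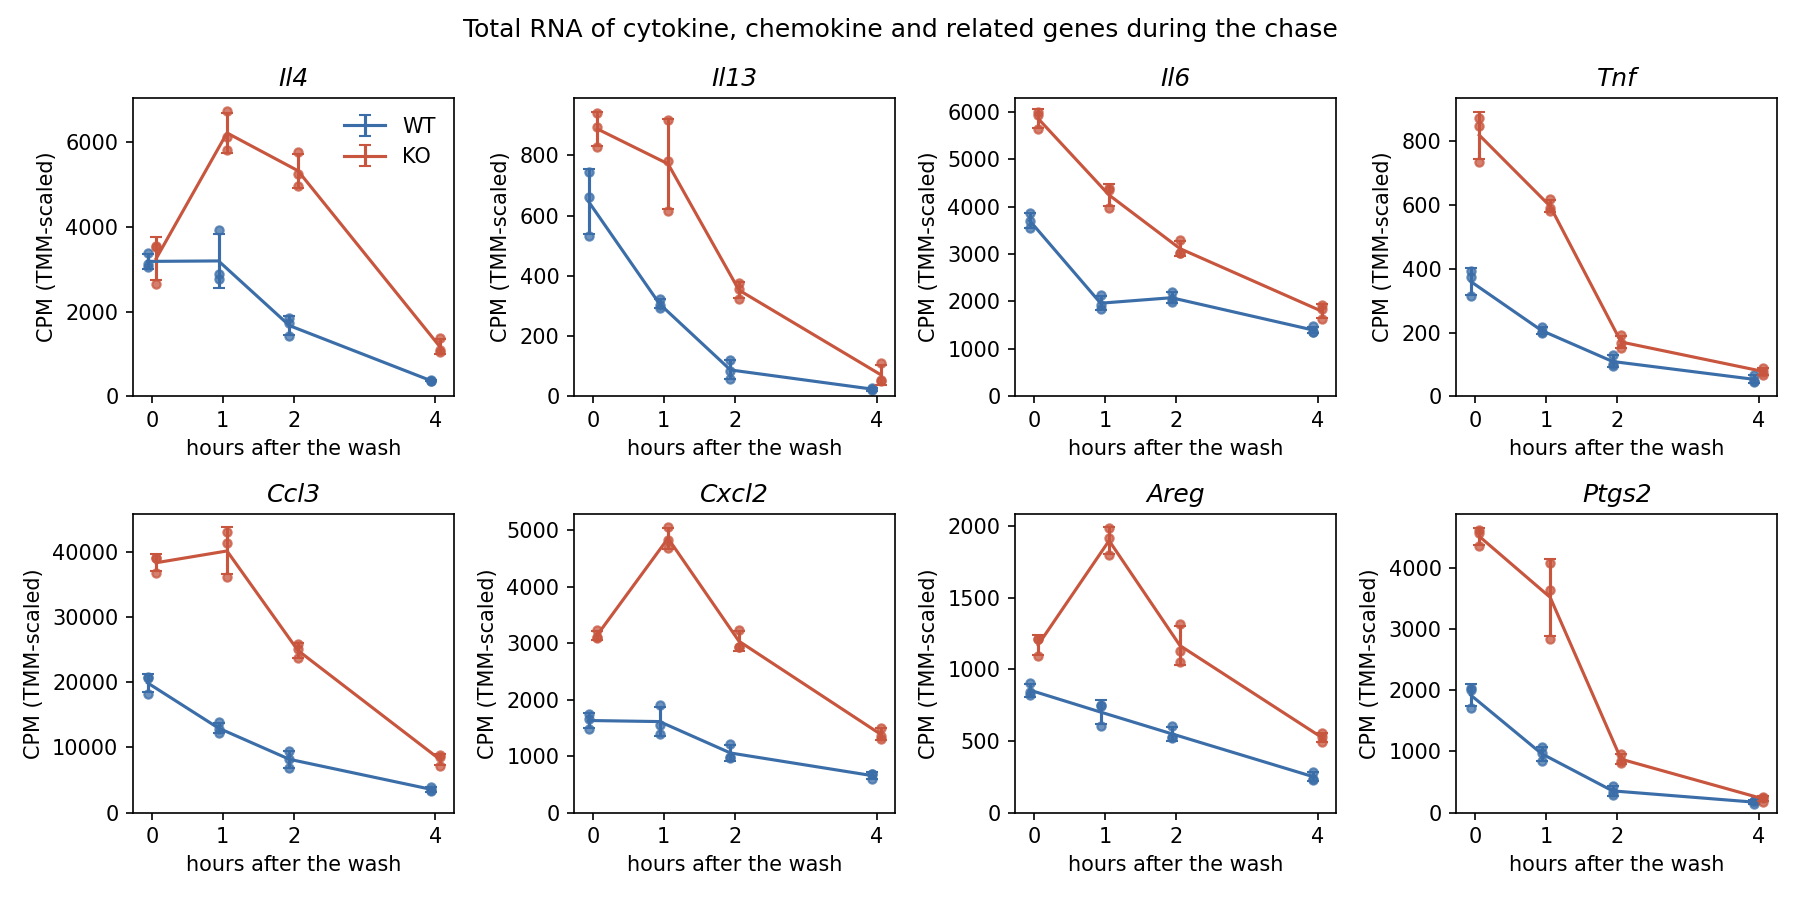
TMM-scaled CPM of 8 mediator genes against hours after the wash, 1 point per library, with lines through the mean ± SD of 3 libraries (WT blue, KO red). Il4 starts alike, at 3181 CPM in WT and 3246 in KO, and stands at 367 and 1174 at 4 h, while Ptgs2 starts at 1920 and 4515 and ends at 170 and 226.

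At 4 h, the longest chase, the comparison asks which differences were left. The cytokine gap persisted at lower levels. Il4 stood at 1174 ± 173 CPM in KO and 367 ± 14 in WT (1.68 ± 0.12, edgeR adjusted p = 2.65e-15) and Ccl3 at 8177 ± 874 against 3566 ± 350 (1.20, adjusted p = 1.74e-14), while Il13 differed by 1.58 ± 0.20 (adjusted p = 6.35e-07). Il6 (0.36 ± 0.09, adjusted p = 0.0114) and Tnf (0.56 ± 0.15, adjusted p = 0.0329) were still higher, as were Cxcl2 (1.08) and Areg (1.07). Ptgs2 (0.41, adjusted p = 0.125), Plaur (0.39, adjusted p = 0.262), Ccl4 (-0.18, adjusted p = 0.469), Csf1 (-0.25), Zfp36l1 (0.36) and Zfp36l2 (-0.11) did not pass.

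In all, 236 genes passed at 4 h, 122 higher and 114 lower (132 and 86 with library size only, 275 and 216 with DESeq2). A fit of only the groups compared called 47, 38 higher and 9 lower. This count rested on the KO libraries: it was 431 without KO 4 h A, 142 without KO 4 h B and 137 without KO 4 h C. B and C were the smallest libraries. They also held less Actb, 4.15% and 4.27% of reads, against 5.92% in KO 4 h A and 6.61% to 6.86% in WT at 4 h. Reads fell on 11552 and 11924 genes in B and C, 11133 in KO 4 h A and 10863 to 11403 in WT at 4 h. An effect of depth cannot be told from 1 of composition here. Leaving out both leaves KO 4 h A alone, so values from that fit rest on 1 KO library. A call lost there need not have come from B and C. Of the cytokine list, 11 were higher and 1, the chemokine gene Ccl6 (-0.44), lower (12 and 4 adjusted over the list alone; camera adjusted p = 3.3e-09). Of the TTP targets, 12 were higher and 1, Zfp36, lower (16 and 2 adjusted over the list alone; adjusted p = 1.99e-10), including Phlda1 (0.80) and the phosphatase gene Dusp1 (0.67). Of the macrophage markers, 7 were higher (11 adjusted over the list alone; median log2 1.57, adjusted p = 3.02e-25), and their sum was 1573 ± 196 CPM in KO and 764 ± 47 in WT. Apoe (3.05 ± 0.19), Mrc1 (4.76 ± 1.04), Ctss (1.67) and Lyz2 (1.07) were among them. The largest increases also took in Fabp4 (4.88 ± 1.08), Tmem65 (4.79 ± 1.15), the lysosomal protease gene Ctsl (4.46 ± 0.22, edgeR adjusted p = 1.66e-20), Ankrd33b (4.39 ± 1.13), the endocytic adaptor gene Dab2 (4.14 ± 0.88) and Arg1 (3.51 ± 0.82), the arginase of macrophages activated by type 2 cytokines. Tmem65 and Ankrd33b did not pass without KO 4 h B and C. Ctsl stood at 226 ± 5 CPM in KO and 10.3 ± 2.5 in WT.

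Decreases at 4 h were led by G0s2, an inhibitor of fat breakdown (-3.41 ± 0.88), Zfp707 (-2.43 ± 0.52), Pdzd4 (-2.27 ± 0.62), Atxn1l (-1.98 ± 0.39), Micall1 (-1.83 ± 0.29), the lipoxygenase gene Alox15 (-1.71 ± 0.27, edgeR adjusted p = 5.26e-05) and Tmem9 (-1.70 ± 0.44), while B4galnt4, with 0 reads in KO, was at least 48.4-fold lower. Of these, only Atxn1l, Micall1 and Alox15 passed without KO 4 h B and C. Of the 45 RNA decay regulators, 2 were lower (3 adjusted over the list alone), Zfp36 and the deadenylase subunit gene Pan3. Pan3 differed by -1.09 ± 0.28 and did not pass without KO 4 h B and C. For this list the camera adjusted p was 0.000651, or 0.0431 with an estimated correlation. Its median was -0.27, and -0.20 without KO 4 h B and C. Of the basophil identity genes, Hdc, which makes histamine, was higher (0.32, not without KO 4 h B and C) and Alox15 lower. Adjusted over the list alone, 3 were higher and 10 lower. For this list the camera adjusted p was 0.0072, or 0.0407 with an estimated correlation. Its median was -0.08, and -0.12 without KO 4 h B and C. The mast cell list tested lower, with Tpsb2 (-0.94) called (camera adjusted p = 0.0342, adjusted p = 0.0657 with an estimated correlation). Its median was -0.11, and -0.21 without KO 4 h B and C.

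Ribosomal protein RNAs were higher in KO at 4 h, with 13 of 62 past the threshold (20 adjusted over the list alone; median 0.21, camera adjusted p = 4e-10, adjusted p = 0.274 with an estimated correlation). Examples are Rps23 (0.81 ± 0.14, edgeR adjusted p = 0.00014), Rps27a (0.64 ± 0.13) and Rpl13a (0.55 ± 0.12). Without the small libraries KO 4 h B and C, which leaves KO 4 h A alone, the median of the ribosomal list was 0.06. In that fit the medians were 1.26 for the macrophage markers, 0.12 for the cytokines and 0.17 for the TTP targets. Of the 47 oxidative phosphorylation genes, 2 were higher, Ndufa6 (0.64) and Cox7c (0.43) (6 adjusted over the list alone; adjusted p = 0.00316, adjusted p = 0.115 with an estimated correlation). The median of this list was 0.17, and 0.15 without KO 4 h B and C. Immediate early genes did not pass as a list (adjusted p = 0.342), with Atf3 (1.24 ± 0.35), Egr2 (1.08 ± 0.28) and Dusp1 higher and Egr3 (-0.43) lower, nor did the NFAT list (adjusted p = 0.103). Without KO 4 h B and C, Dusp1 differed by 1.04, and Atf3, Egr2 and Egr3 did not pass on the 1 KO library left.

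Across the 4 times, 297 genes passed at 1 or more, 31 were higher in KO at every time, and 0 were lower at every time. The 31 hold the mediators Il6, Tnf, Ccl3, Cxcl2, Areg, Il1b, Ccl2, Ccl7 and Hbegf, and the macrophage-type genes Apoe, C1qb, C1qc, Ctss, Ctsb, Ctsl, Lyz2, Cd36, Gpnmb, Mmp12, Lpl, Acp5 and Lgals3. Of those higher at 0 h and at 4 h, 38 were shared, against 0.547 for independent lists. Both lists come from 1 fit and may share animals or cultures, so independence need not hold and this is no test. The remaining lists passed at none of the 4 times: NF-kB targets (2 members higher at 0 h, Pim1 and Plk3), lipid mediator synthesis, survival and apoptosis, p53 response, the unfolded protein response, interferon response, glycolysis, and markers of NK and T cells, neutrophils, eosinophils, and erythroid and progenitor cells. The mitochondrial list had 0 members in the table. Members of these called at 4 h were Pmaip1 (0.60, also in the survival list) and Ddit4 (-0.74) for p53, Atf3 for the unfolded protein response, and Rsad2 (-1.24 ± 0.27) and Ifi204 (at least 101-fold higher) for interferon. Others were Mgst2 (at least 39.5-fold higher, with 4 h reads only in the small KO 4 h libraries B and C) for lipid mediators, Alox15 for lipid mediators and eosinophils, Itga2b (-0.37) for progenitors, and S100a8 (0.53) and S100a9 (0.40) for neutrophils. Of all these, only Rsad2, Ifi204 and Alox15 passed without KO 4 h B and C. Lists with 0 called members at 4 h are shown by their most abundant genes, none of them past the threshold. These were Nfkbia (0.06) and Pim1 (-0.13) for NF-kB and Pkm (0.06) and Aldoa (0.05) for glycolysis. For the cell cycle they were Hmgb2 (-0.22) and Pcna (-0.11), and Gzmb (-0.11) and Nkg7 (-0.30) for NK and T cells. The dendritic and B cell list also passed at 1 h (adjusted p = 0.0098, adjusted p = 0.0355 with an estimated correlation), with Cd74 and H2-Aa called, and at 2 h (adjusted p = 0.0432, adjusted p = 0.0689 with an estimated correlation), where its median was 0.33 and its mean -0.27. The cytokine, TTP target and macrophage lists also passed at all 4 times with an estimated correlation, where their largest adjusted p values were 0.000206, 0.000872 and 2.17e-06. Over the 92 pairs of list and time, 33 passed, 26 up and 7 down, and 19 passed with an estimated correlation, 17 up and 2 down. In 23 pairs the median, mean and test differed in sign, and 3 of these passed: the NFAT list at 0 and 1 h and the dendritic and B cell list at 2 h.

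**Figure D2:**
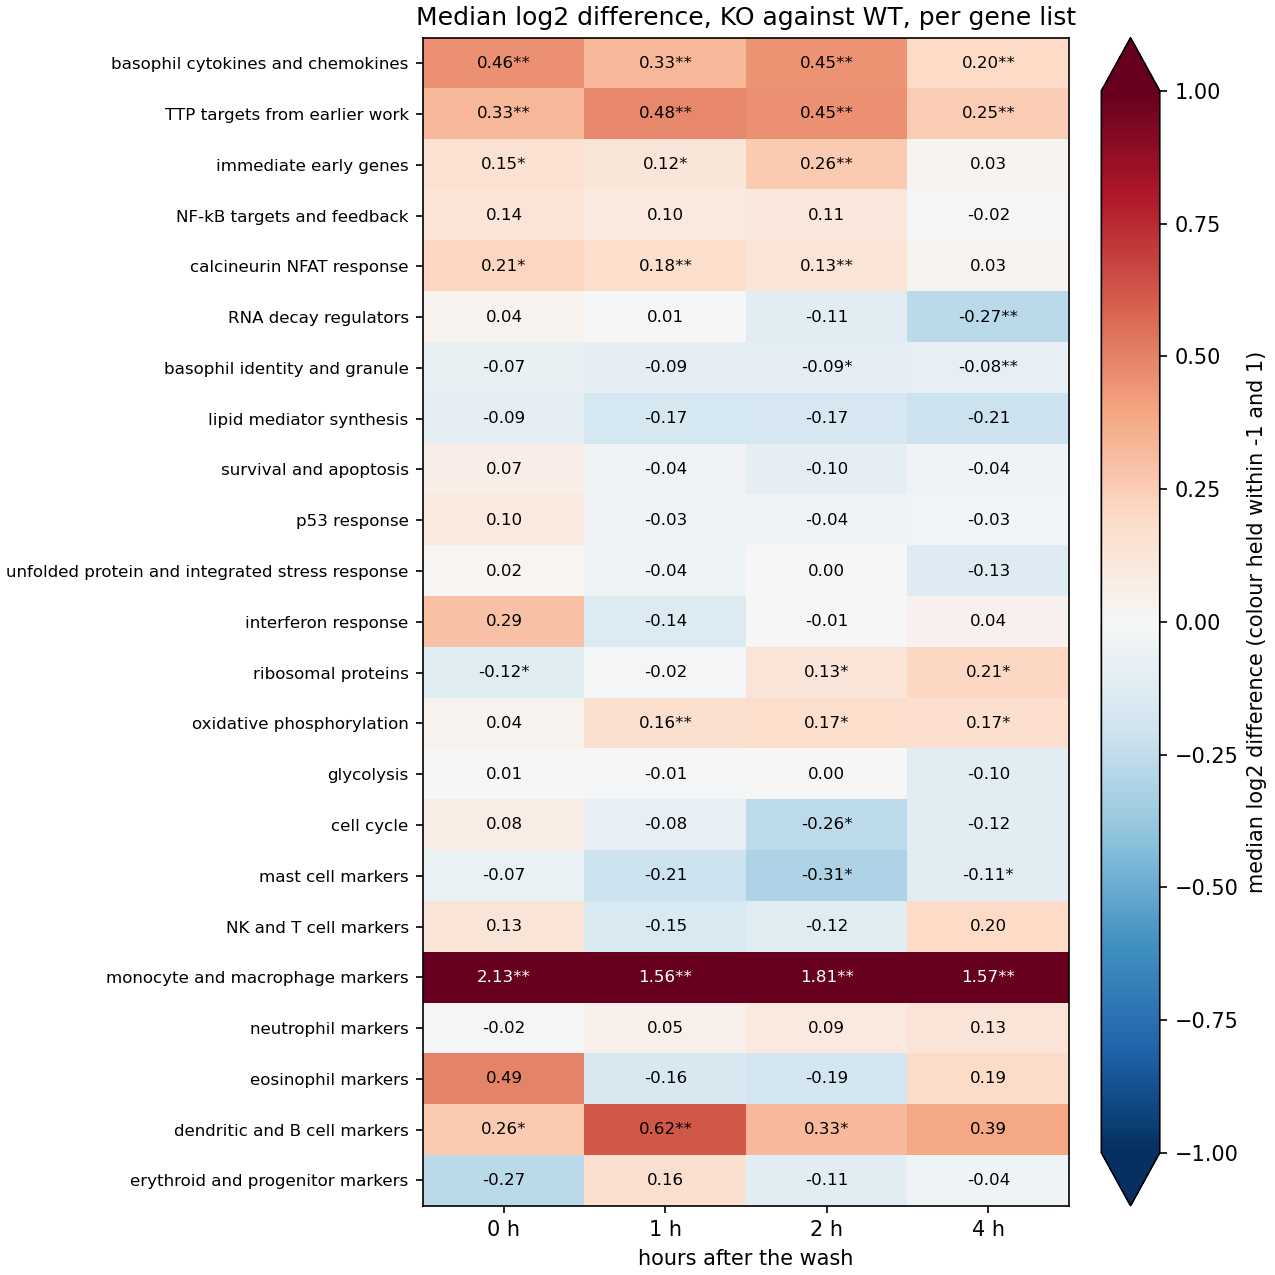
Median log2 change, KO against WT, of 23 gene lists (down) at 0, 1, 2 and 4 h (across), with colour held within -1 and 1; 1 star marks a camera adjusted p under 0.05 with a preset correlation and a pair of stars also with an estimated one. The macrophage list has medians of 2.13, 1.56, 1.81 and 1.57, and the TTP targets 0.33, 0.48, 0.45 and 0.25.

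The chase within each genotype shows how RNA levels changed after the wash. All groups were given antigen, so a fall of the antigen response cannot be told from other changes with time. In WT cells several transcription factor and mediator genes fell steeply over 4 h. Among transcription factors were Nr4a1, an orphan nuclear receptor induced by antigen receptors (-5.14 ± 0.16), Fosb (-6.14 ± 0.77) and Egr3 (-4.25). Among mediators were Il13 (-4.75), Ptgs2 (-3.49), Il4 (-3.12), Tnf (-2.76), Csf1 (-2.49) and Ccl3 (-2.48). In KO cells Nr4a1 (-5.45), Egr3 (-4.89), Alox15 (-4.38), Ptgs2 (-4.32), Il13 (-3.63) and Tnf (-3.39) fell as well, and Il4 fell less (-1.47 ± 0.12). The eosinophil attractant gene Ccl24 rose in both, from 0.373 ± 0.646 to 27.7 ± 7.0 CPM in WT (6.21 ± 0.86) and from 0 reads to 83.8 ± 7.9 CPM in KO, at least 1421-fold. Arg1 rose by 3.94 ± 0.92 in WT and 5.06 in KO.

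In WT 302, 1300 and 2165 genes passed at 1, 2 and 4 h against 0 h (136, 463 and 875 higher; 166, 837 and 1290 lower), and in KO 354, 1279 and 2336 (159, 533 and 964 higher; 195, 746 and 1372 lower). These directions depend on scaling. With library size only, the median of all genes shifted up by 0.08, 0.25 and 0.32 in WT and 0.00, 0.21 and 0.37 in KO, and the calls became 199, 1033 and 1831 higher and 118, 414 and 748 lower in WT, and 188, 1002 and 2156 higher and 156, 447 and 818 lower in KO. Of the immediate early genes, 30 of 44 were lower at 4 h and 1 higher in each genotype. Of the TTP targets, 29 were lower and 3 higher in WT, and 28 lower and 2 higher in KO. Of the cytokines, 13 were lower and 9 higher in WT, and 14 lower and 7 higher in KO. Ribosomal protein RNAs were lower in WT (59 of 62, or 40 with library size only) and in KO (37, or 12 lower and 9 higher with library size only), and neutrophil markers were lower in WT (12 of 18) and KO (8, with 1 higher). Of the macrophage markers, 7 were lower in each genotype. Large changes by the naming rule in WT were also those of Fam83g (-6.30) and Sag (7.53), with Edn1, Col18a1 and Mroh2a at least 218-fold, 390-fold and 215-fold higher and Fzd5 and Grhl1 at least 161-fold and 158-fold lower. In KO they were those of Mrgpra2b (-5.78) and Hic1 (-5.37), with Adgrb3, Kcnmb4 and Ank3 at least 619-fold, 570-fold and 523-fold higher and B4galnt4 at least 94.0-fold lower.

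The interaction contrast asks whether the change from 0 to 4 h itself differed between genotypes. It did so for Il4, which fell less in KO (difference 1.65 ± 0.16, edgeR adjusted p = 2.15e-09), and for Ctsl (2.30 ± 0.28, edgeR adjusted p = 5.26e-07), which fell by 3.29 in WT on the log2 scale and by 0.99 in KO. Phlda1 (1.17 ± 0.26) also fell less in KO. The ribosomal gene Rpl36a (difference 1.02 ± 0.21) fell in WT (-0.79) but did not pass in KO (0.24), and S100a8 (0.81 ± 0.18) likewise (-0.57 and 0.25). A larger fall in KO held for Zfp707 (-3.05 ± 0.70), Micall1 (-1.74 ± 0.40), Alox15 (-1.66 ± 0.37), Ptgs2 (-0.83 ± 0.19) and the macrophage growth factor gene Csf1 (-0.54 ± 0.12). Of the genes named here, Rpl36a, S100a8 and Zfp707 lost their calls for KO against WT at 4 h without KO 4 h B and C. That fit leaves KO 4 h A alone. Ptgs2 and Csf1 had not passed for KO against WT at 4 h. Interaction calls of single genes in that fit are not given here. In all 25 genes passed edgeR, 11 higher and 14 lower (22 and 11 with library size only), and 178 passed DESeq2. The count was 8 without WT 0 h B, 10 without KO 0 h A, 15 without KO 0 h B, 114 without KO 4 h A, and 16 without KO 4 h B or without KO 4 h C.

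**Figure D3:**
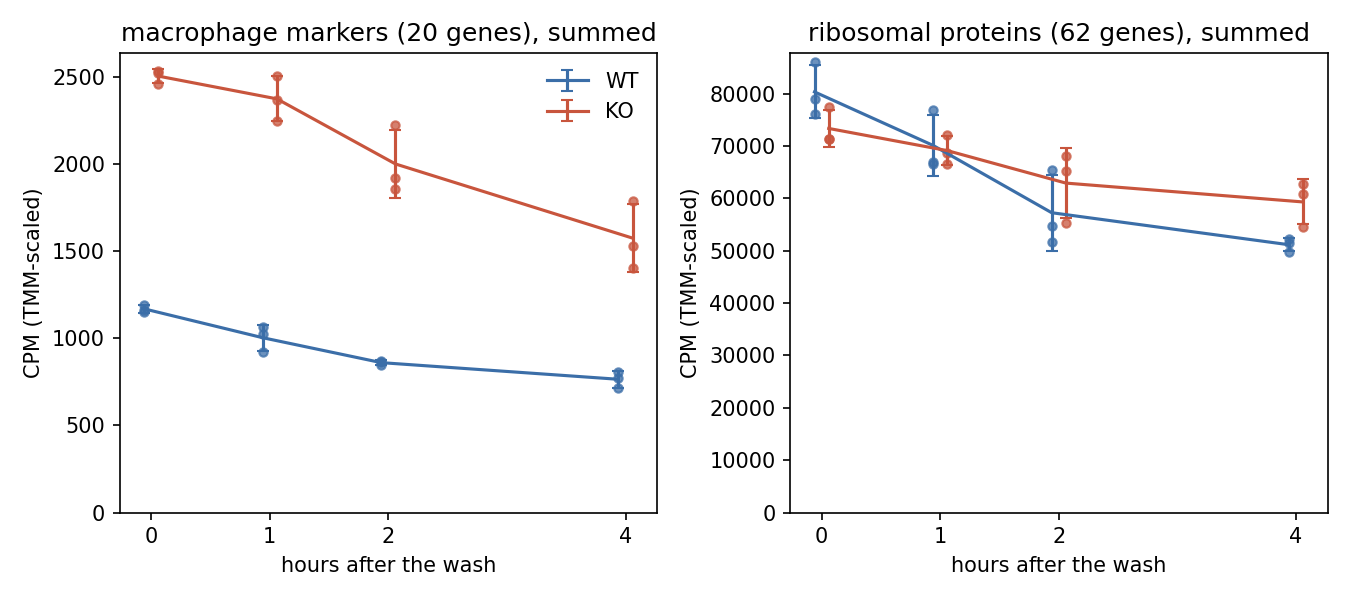
Summed CPM of 20 macrophage markers and of 62 ribosomal protein genes against hours after the wash, with 1 point per library and lines through the mean ± SD of 3 libraries (WT blue, KO red). The macrophage sum is 2503 CPM in KO and 1168 in WT at 0 h, and 1573 and 764 at 4 h.

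TTP binds AU-rich motifs in 3' UTRs, and the last comparison asks whether genes with such motifs differed as a group. The 4096 tested genes with TATTTAT had a median log2 change of 0.01 at 0 h, against 0.00 for 8642 others, and the 1152 genes with the longer TTATTTATT had 0.04. Motif membership was permuted within bins of 3' UTR length to test the difference in mean z values, not in medians. At 0 h this difference was 0.15 for TATTTAT and 0.21 for TTATTTATT, against 0.04 and 0.03 expected from 3' UTR length. At 1 h it was 0.13 and 0.20, against -0.02 and -0.02 expected. Each had a permutation p of 1e-04, the smallest these permutations can give (adjusted p = 2e-04). Permuting genes takes them as independent of each other. At 2 h the permutation p was 0.0116 for TATTTAT and 0.0042 for TTATTTATT (adjusted 0.0155 and 0.00672). The medians of genes with a motif were then 0.00, and for TATTTAT the difference in mean z values of -0.01 lay above the -0.06 expected from 3' UTR length. At 4 h the permutation p was 0.0412 and 0.0482 (adjusted 0.0471 and 0.0482), with differences in mean z values of -0.01 and 0.03 against -0.06 and -0.05 expected. Camera called 0 of the 8 tests, with a smallest unadjusted p of 0.0871 and a smallest adjusted p of 0.487, or 0.231 with an estimated correlation, and fry also called 0. Of the genes higher in KO at 0 h, 23 held TATTTAT and 35 did not (0.562% and 0.405% of such genes, Fisher adjusted p = 0.415), and 11 held TTATTTATT and 47 did not (0.955% and 0.406%, adjusted p = 0.0953). At 1 h these shares were 0.586% and 0.324% (adjusted p = 0.0979), and 0.868% and 0.363% (adjusted p = 0.0953). At 2 h they were 0.488% and 0.382% (adjusted p = 0.506), and 0.781% and 0.380% (adjusted p = 0.106). At 4 h they were 0.952% and 0.949% (adjusted p = 1), and the other way for TTATTTATT, 0.868% and 0.958%. Among the genes fixed by name, Tnf held 8 TATTTAT motifs, Cxcl2 7, Ptgs2 6, Il4 2, Zfp36, Zfp36l1 and Zfp36l2 3 each, Il6, Il13, Areg, Ccl3, Ccl4 and Csf1 1 each, and Plaur 0.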

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

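In this part, the tests of the neutrophil list, of Il4 at 0 h and of the splits that mix genotypes at both times were chosen only after the result was seen.

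The genotypes' changes from 0 to 4 h differed in total RNA for 25 genes. Of 40 splits of the libraries, 5 gave as many genes for the change from 0 to 4 h (25 in the real split, 48 in the highest other). The 4 others that did keep the genotypes apart at 1 of the times, so the real genotype difference enters their counts and they decide nothing about chance. The 33 splits that mix the genotypes at both times gave at most 3 genes, but mixing also widens the spread, so these do not exclude chance either. By size, the differences in change were led by Ctsl (2.30), Il4 (1.65), Phlda1 (1.17) and Rpl36a (1.02), and downward by Edn1 (-9.09), Col18a1 (-9.02), Zfp707 (-3.05) and Micall1 (-1.74). Edn1 and Col18a1 had 0 reads in WT at 0 h, so their fitted values are no bound.

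The other comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. For KO against WT at 0, 1, 2 and 4 h the real counts were 68, 65, 67 and 236 and the highest others 2, 0, 0 and 17. For 1, 2 and 4 h against 0 h they were 302, 1300 and 2165 in WT, with highest others 2, 1 and 1, and 354, 1279 and 2336 in KO, with highest others 1, 0 and 0.

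Macrophage transcripts were higher in KO at every time. If a lower share of basophils raised all other cell types alike, neutrophil markers would rise with the macrophage markers. The neutrophil list had a median log2 of -0.0203 at 0 h (bootstrap over its genes -0.23 to 0.51), against 2.13 (0.94 to 2.66) for the macrophage list. For neutrophil markers this argues against such an even rise, but not against macrophage-lineage cells in place of basophils. Which cells gave these neutrophil RNAs was not measured. Medians of other lists at 0 h were 0.49 for eosinophils, 0.26 for dendritic and B cells and 0.13 for NK and T cells. They were -0.07 for mast cells and -0.27 for erythroid and progenitor cells. The basophil identity list had a median of -0.07 and did not pass at 0 h. The bootstrap gives the spread between genes of a list, not between cultures. More macrophage-lineage cells in the KO cultures stays open as a candidate source. Within groups, the deviations of 17 markers were only weakly correlated, with a mean correlation of 0.0604. This lay above the 95th percentile of 0.0486 in 9887 random lists, whose median was 0.00139. Genes induced together inside basophils could be correlated as well, so this does not tell more cells from induction. Enrichment of CD49b-bearing cells with magnetic beads before the antigen pulse would remove macrophage-lineage cells that lack CD49b, and how many were left was not measured. Induction of these genes inside basophils was not tested. Of the most abundant such transcripts, Lyz2 stood at 976 ± 14 CPM and Apoe at 366 ± 32 in KO at 0 h. Whether such cells, if left after the enrichment, are the source of the Il4 difference stays open: Il4 differed by 0.0299 at 0 h (0.256 with 2 SE added), where the macrophage gap was already present, but such cells could gain Il4 RNA during the chase.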

How the results depend on the processing

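The alternative without the 2 smallest libraries was chosen after seeing the data. No paired analysis was possible because the table's columns carry letters that nothing ties to the labels' replicate numbers, so the planned replicate block was not run. A term for the letters themselves, tried after seeing the data, is not given here, because no label says that a letter pairs libraries. Other settings for decay slopes, half-lives and the labelled fraction are not given, as those values were not used here. Counts stayed within 1.5 times of those reported under other size factors and under library size only. They rose with DESeq2 to 227, 202, 228 and 491 for KO against WT at 0, 1, 2 and 4 h, 601 and 655 for 1 h against 0 h in WT and KO, and 178 for the interaction. Without a count filter they were 123, 108 and 127 at 0, 1 and 2 h and 89 for the interaction, which was 13 for genes of at least 50 reads. With only the groups compared they were 116, 41 and 47 at 0, 2 and 4 h and 16 for the interaction. Without KO 4 h B and C, where KO 4 h A is assumed to vary like the other groups, they were 134, 120, 146 and 130, then 454 for WT at 1 h and 58 for the interaction. Leaving out each library gave 50 to 71, 56 to 63, 45 to 99 and 137 to 431 for KO against WT, 204 to 268, 970 to 1153 and 1713 to 1897 in WT, 243 to 303, 973 to 1062 and 1906 to 2294 in KO, and 8 to 114 for the interaction (extremes without WT 0 h B and KO 4 h A). With an estimated correlation 19 of 33 list calls held, with fry 37 were made and with library size only 35. With at least 2 TATTTAT motifs against none 0 motif tests passed. The difference of Mgst2 at 4 h was gone without KO 4 h B and C (0, with no 4 h reads left). Among named genes, leaving out single libraries kept 817 values on their side of the threshold, lost 168 calls, gained 4 and moved 7 values not past it, fits of only the groups compared kept 102, lost 50 and gained 4, and DESeq2 kept 149, lost 6 and gained 3. The cause of the moves was not tested beyond the fewer genes or libraries that some settings hold by construction.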

Other observations

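The test of the first hour below was chosen only after the result was seen. Some lists not yet described had members past the threshold between 0 and 4 h, and these lists were not tested as groups. Over all 12936 genes, 875 were higher and 1290 lower at 4 h in WT, and 964 higher and 1372 lower in KO. Of 28 survival and apoptosis genes, 8 were higher and 5 lower at 4 h than at 0 h in WT, and 5 higher and 5 lower in KO. Of 25 p53 response genes, 7 were lower and 1 higher in WT, and 8 lower and 1 higher in KO. Of 27 genes of the unfolded protein and integrated stress response, 9 were lower and 2 higher in each genotype, or 6 higher and 4 lower in WT and 3 higher and 4 lower in KO with library size only, where WT turns toward higher. Ccnd3, a cyclin that drives entry into the cell cycle, rose by 0.87 in WT and 1.19 in KO, and the proliferation clamp gene Pcna was lower by -1.39 in WT and -1.73 in KO. The monocyte attractant gene Ccl7 rose by 2.06 in WT and 1.84 in KO and was higher in KO at all 4 times. Pcna and Ccl7 were chosen after their values were seen. The macrophage markers Adgre1, Ly6c2, Ccr2, Cd14 and Cx3cr1, chosen after their values were seen, did not pass at any time.

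The difference between the genotypes in TTP target RNA was larger at 1 h than at 0 h. The median difference between the genotypes' changes from 0 to 1 h was 0.232 over 49 TTP targets, above 0 for 31 of them (camera p = 6.03e-05, and p = 0.00713 with an estimated correlation). Of these, 4 passed edgeR's threshold, Areg (0.98 ± 0.16, adjusted p = 0.000726), Il4 (0.93 ± 0.16, adjusted p = 0.00235), Ccl3 (0.68 ± 0.12, adjusted p = 0.00378) and Plaur (1.09 ± 0.22, adjusted p = 0.0186), and 11 adjusted over the list alone. In all 8 genes passed, 594 at an unadjusted p under 0.05. These values restate the pattern and do not test whether slower loss in KO lies behind it. From 0 to 1 h Il4 rose by 0.94 in KO (adjusted p = 7.72e-08) and changed by 0.01 in WT, and Areg rose by 0.70 in KO (adjusted p = 2.83e-05). Ccl3 changed by 0.07 in KO and -0.62 in WT.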
